A study of Populus tremula x Populus alba with 6 samples.

How the data were processed

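Chromatin immunoprecipitation sequencing (ChIP-seq) was done on mesophyll protoplasts, which are leaf cells freed of their walls, of the hybrid poplar Populus tremula x Populus alba. The cells transiently expressed PtrbHLH011, a basic helix-loop-helix (bHLH) transcription factor, fused to a Myc epitope tag. The labels list 6 libraries, namely 3 anti-Myc ChIP libraries and 3 input libraries that had no antibody step, each group numbered as biological replicates 1 to 3. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sheared by sonication, and libraries were made with a ThruPLEX kit.

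The values analysed here are peak tables, with 1 table for the P. alba and 1 for the P. tremula chromosome sequences of the hybrid, called subgenomes below. BWA 0.7.17.2, MACS2 2.2.7.1 and ChIPseeker 1.18.0 are named in the submitters' processing notes, and the peak names in the deposited tables show a duplicate-marking step. The genome build, the gene annotation release, the peak calling options and the use of the input libraries as control are not given in the sources used here. Per the file headers, each peak carries its start, end and summit, a pileup (the read coverage signal at the summit), a fold enrichment ratio over the caller's local background, −log10 p and q values, and the gene annotation that ChIPseeker assigned. All peak names in both deposited tables carry the same single tag, which matches no library label, so neither the replicate nor the pooling behind a table could be told, and no value belongs to 1 library. In neither list did a peak have a −log10 p value below 3.00 in the deposited columns, the mark of a p threshold rather than a q threshold.

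Every peak stood in 2 rows of its deposited table, once with its gene name as NA and once with the gene identifier repeated as the name, and was counted once here. The 37950 and 34080 rows thus gave 18975 P. alba and 17040 P. tremula peaks. Peak numbers ran to 19162 and 17195, and 187 and 155 numbers in those ranges belong to no peak analysed here. Positions are given from 1, as in the tables, on the sequence of the named subgenome, and cannot be exchanged between the subgenomes.

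The promoter class is the authors' own and covers peaks up to 3 kb to either side of an annotated start, so it includes peaks inside genes. Distances of summits from gene starts and ends were computed from the tables' gene coordinates. The background behind each fold was recovered as (pileup + 1) / fold − 1, with 1 read as the caller's pseudocount. From this background a Poisson −log10 p within 0.01 of the deposited one was obtained for 99.9% of the peaks in each list. No reference genome or annotation was used here, so that motif searches at summits, a background of genes without a peak and a distribution of random positions were not available. The tables pair no gene identifier with a symbol, a description or an Arabidopsis locus. The 9 gene lists fixed beforehand could therefore not be matched: iron uptake and transport, iron regulators, cellulose, xylan, lignin, secondary wall regulators, photosynthesis, protoplast stress and immunity, and circadian and light genes, 169 genes in all, had 0 matches, and no list was tested. For the same reason at most 4 identifiers are printed, and other peaks are named by position. The planned ChIP against input test and the overlap of replicates need values per library and were not made.

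Shares are given with exact (Clopper-Pearson) 95% binomial intervals and were compared with Fisher's exact test, two-sided, beside sample odds ratios with normal-approximation 95% intervals. Median folds of promoter and other peaks were compared with a two-sided permutation test of 100000 resamples. Counts of summits in windows of equal width were compared with an exact two-sided binomial test. These tests treat peaks as independent and measure counting error within a list, not the spread between replicates. Peaks of the 2 lists were paired when they were annotated to the same gene identifier and their summits lay within 100 bp of the same distance from that gene's start, each peak used once and the closest pairs first. On simulated data made by moving 11430 P. alba peaks by known distances, all under the 100 bp tolerance, 99.97% were recovered. Gene identifiers were kept, so this checks the procedure only and does not measure false pairings between the subgenomes. With folds first shuffled over all peaks, the permutation test gave p = 1, a value that the tied medians fix in advance. With promoter folds then raised 1.5 times, the permutation test gave p = 0.0005, the smallest its 2000 test resamples allow.

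The peaks named in the text were chosen by a rule fixed before the data were examined: for each subgenome, the promoter peaks of the 10 genes with the highest fold. The poplar gene closest to Arabidopsis bHLH11, also in the rule, could not be found without gene names. The peaks of highest pileup and of highest fold outside promoters were added after their values were seen. Alternatives fixed at the same time were a q threshold of 0.01, peaks at or above the median fold, merged intervals, promoters within 1 kb or 2 kb, −log10 q as the measure of strength, and genes called within 1 kb or by any peak. The windows around starts and on chromosome 13, the pairing of peaks, the recovered background, the comparison of peaks with a fold of 5 or more and the strata of fold and pileup were chosen after seeing the data. Analyses used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

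Depth per library cannot be read from peak tables. The pileup gives the depth at each peak: the median summit held 7 reads in both lists, for which an exact 95% Poisson interval spans 2.81 to 14.4 reads. Intervals cover counting error only, since duplicate reads and fragments that overlap are not independent molecules.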

Results

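The binding of PtrbHLH011 in poplar was mapped in leaf mesophyll protoplasts, as part of a series on iron deprivation, cell wall formation and the role of this factor. Chromatin bound by the Myc-tagged factor was recovered with an anti-Myc antibody in 3 libraries, and 3 input libraries were made beside them. The deposited peaks comprised 18975 regions on the P. alba subgenome and 17040 on the P. tremula subgenome, the 2 parental chromosome sets of the hybrid. They were annotated to 13403 and 12487 genes. Peak heights, folds and q values are the authors' own, and no between-replicate spread could be computed, because the peaks were not tied to single libraries.

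The first question was how strongly the recovered regions stood above background. Most peaks were short and shallow on both subgenomes. The median peak was 124 bp long on P. alba (25th to 75th percentile 96 to 172 bp) and 128 bp on P. tremula (100 to 176 bp). The median summit held 7 reads in each list, and 78.5% of P. alba and 77.7% of P. tremula summits held fewer than 10. The median fold enrichment was 3.52 on P. alba (25th to 75th percentile 3.02 to 4.02) and 3.53 on P. tremula (3.02 to 4.03). Folds of 10 or more were found at 148 P. alba and 107 P. tremula peaks, and folds of 20 or more at 10 and 6 peaks. The caller's q value exceeded 0.05 at 5191 P. alba peaks (27.4%) and 4619 P. tremula peaks (27.1%), and was at or under 0.01 at 7556 (39.8%) and 6833 (40.1%).

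The background behind these folds was at its lowest value over most of both lists. At 58.9% of P. alba peaks the recovered background equalled the floor of 0.989 reads, within 0.01 reads, and at 56.7% of P. tremula peaks it equalled the floor of 0.985 reads. At those peaks the fold is set by the summit count alone, so that peaks of 5 and 6 reads differ in fold by less than the counting error of either.

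**Figure D1:**
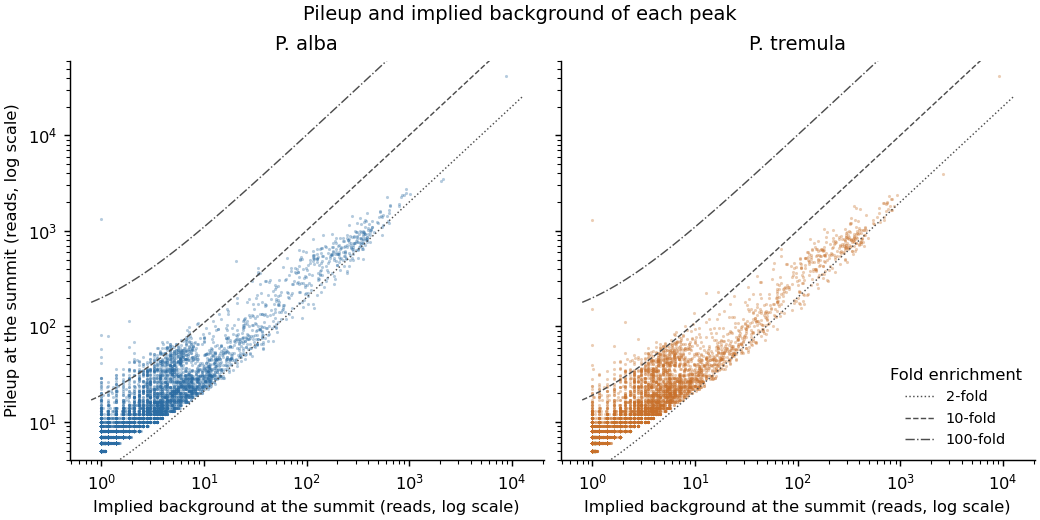
Pileup at the summit (reads, log scale) against the recovered background (reads, log scale) for each peak, 1 point per peak, P. alba left and P. tremula right, with lines of equal fold enrichment. Most points lie at the background floor with fewer than 10 reads, and 1 peak per list lies far above the 100-fold line, at 1347 and 1299 reads.

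Promoters held the majority of peaks on both subgenomes. Of the P. alba peaks, 11506 (60.6%, 95% interval 59.9 to 61.3%) were in the promoter class, and of the P. tremula peaks 10370 (60.9%, 60.1 to 61.6%). Peaks within 1 kb of a start made up 30.0% and 30.4%, those at 1 to 2 kb 17.6% and 17.4%, and the other 2469 and 2222 promoter peaks lay at 2 to 3 kb. Distal intergenic regions held 5121 P. alba peaks (27.0%, 26.4 to 27.6%) and 4590 P. tremula peaks (26.9%, 26.3 to 27.6%). Exons outside the promoter class held 5.60% and 5.52%, introns 3.81% and 3.76%, and regions downstream of genes 2.97% and 2.93%. The promoter shares of the subgenomes, tested over peaks, which are not biological replicates, did not differ detectably by Fisher's exact test (odds ratio 0.991, 95% interval 0.950 to 1.03, p = 0.673). The test takes the lists as independent, which they were not: 66.3% of P. alba peaks had a partner on P. tremula, and 76.6% of the pairs had identical pileups, so near-equal shares say little about a difference between the subgenomes. In paired peaks the promoter shares were 67.6% and 67.7%. Among peaks without a partner, a comparison added after seeing the data, the share was higher on P. alba, at 47.0% (45.8 to 48.2%) of 6399 peaks against 41.7% (40.2 to 43.1%) of 4464 on P. tremula (odds ratio 1.24, 1.15 to 1.34, Fisher's exact p = 4.00e-08). This gap goes arithmetically with near-equal whole-list and paired shares and unequal paired fractions (66.3% of P. alba and 73.8% of P. tremula peaks). That link does not tell whether the subgenomes differ in promoter share, and the cause of the gap was not tested. Pairing by distance from a gene start can favour peaks close to genes, to an extent not measured here. No background of random genomic positions was available, so these shares were not tested for enrichment.

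**Figure D2:**
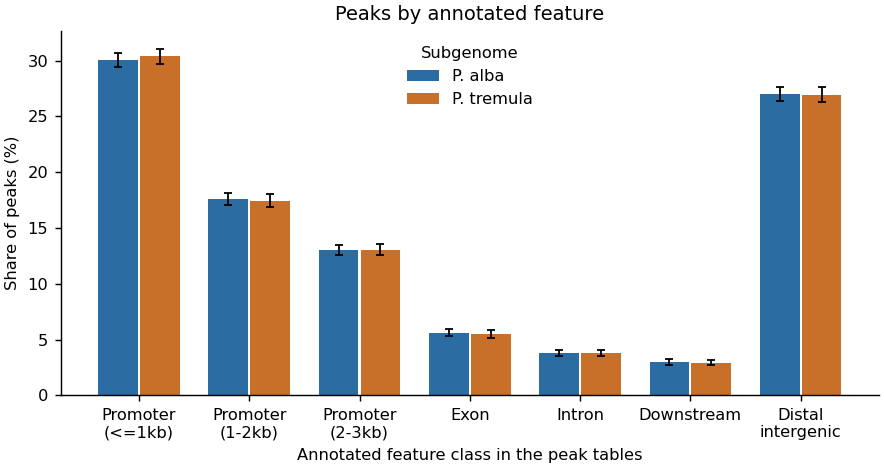
Share of peaks (percent) in each annotated feature class for P. alba (18975 peaks) and P. tremula (17040 peaks). Bars are shares and whiskers are exact 95% binomial intervals, which overlap between the subgenomes in every class.

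The authors' promoter class reaches to both sides of the start, and most of its summits lay at or past the start. Upstream summits made up 38.2% of P. alba and 38.8% of P. tremula promoter peaks, and the summit lay inside the gene in 51.1% and 50.6%. Summits were densest at the start itself. Within 250 bp of a start lay 2237 P. alba summits (11.8%, 11.3 to 12.3%), near 2201 genes, and 2028 P. tremula summits (11.9%, 11.4 to 12.4%), near 2001 genes. The neighbouring windows from 250 to 500 bp, of the same total width, held 1201 and 1100. The near windows thus held 1.86 times as many summits on P. alba (95% interval 1.74 to 2.00, exact binomial p = 8.58e-71) and 1.84 times as many on P. tremula (1.71 to 1.99, p = 1.32e-62). The fullest 100 bp bin in both lists was the first past the start, with 587 and 521 summits. Of the summits within 250 bp, 43.8% on P. alba (41.7 to 45.9%) and 44.5% on P. tremula (42.3 to 46.7%) were upstream, fewer than the downstream ones (exact binomial p = 3.98e-09 and 7.17e-07). Upstream of the start the count fell off more steeply, to 428 P. alba summits at 250 to 500 bp upstream against 773 downstream.

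**Figure D3:**
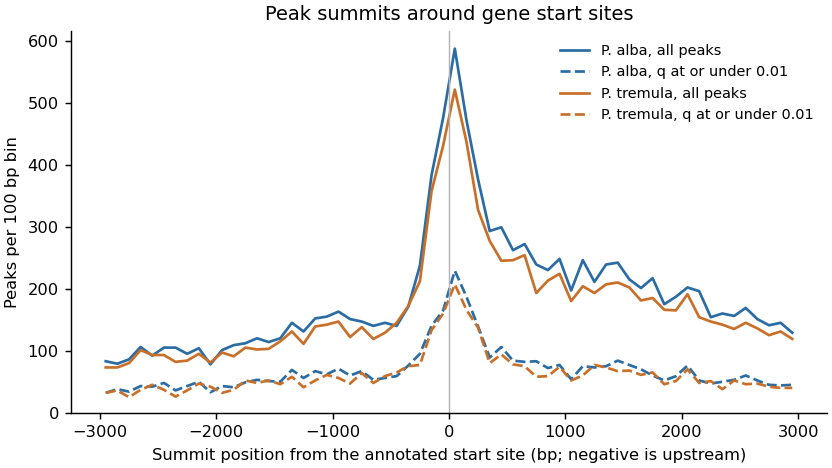
Number of peak summits per 100 bp bin against the position from the annotated start site (bp, negative is upstream) for both subgenomes, for all peaks (solid lines) and for peaks with q at or under 0.01 (broken lines). The bin just past the start is the fullest, with 587 P. alba and 521 P. tremula summits.

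Promoter peaks were not stronger than the others. The median fold was 3.52 in promoter peaks and in other peaks of P. alba, and 3.53 in both on P. tremula (permutation p = 1 for each), medians that the tied folds of shallow peaks hold equal. Folds of 5 or more were less frequent in promoters. They were reached by 7.21% of the P. alba promoter peaks against 9.75% of other P. alba peaks (odds ratio 0.720, 0.649 to 0.799, Fisher's exact p = 7.59e-10). The P. tremula shares were 7.25% and 9.37% (odds ratio 0.756, 0.677 to 0.845, Fisher's exact p = 9.53e-07). At folds of 5 to under 10, promoters held 52.8% of P. alba peaks (50.1 to 55.4%) and 54.0% of P. tremula peaks (51.2 to 56.8%). Below a fold of 3 their shares were also low, at 50.3% (48.0 to 52.6%) and 50.9% (48.6 to 53.1%). Those peaks lay over a raised background (median 3.46 and 3.91 reads), so a fold under 3 does not mark the shallowest peaks. At folds of 10 or more promoters held 58.1% (49.7 to 66.2%) and 61.7% (51.8 to 70.9%), intervals that include the shares in the whole lists. Among the other classes, distal intergenic peaks reached a fold of 5 at 12.0% on P. alba and 11.4% on P. tremula, and exon peaks at 2.26% and 1.92%. With −log10 q as the measure of strength, the promoter median was lower, at 1.44 against 1.61 on P. alba and 1.42 against 1.60 on P. tremula (permutation p = 1e-05 for each, the smallest the resamples can give).

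The position of peaks differed with their depth. Among summits of 5 to 9 reads, the promoter share was 65.4% on P. alba (64.7 to 66.2%) and 66.0% on P. tremula (65.2 to 66.8%). From 20 to 49 reads it was 37.97% (35.3 to 40.7%) and 39.5% (36.8 to 42.3%), and distal intergenic peaks made up 56.3% and 54.2%. From 200 reads on, the promoter share was 77.1% (72.2 to 81.5%) and 78.8% (73.8 to 83.1%). Median folds in this deepest class of 332 and 320 peaks were 2.91 and 2.79. Its median recovered background was 200.1 and 207 reads. At least 93 and 99 of its peaks lay between 14600000 and 14899999 on chromosome 13. The intervals treat peaks as independent and take no account of this cluster. How far the cluster sets the shares of the deepest class was not tested. Summits within 250 bp of a start made up 13.2% and 13.4% of the shallowest class, 3.79% and 3.91% of the class of 20 to 49 reads, and 19.3% and 20.3% of the deepest.

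The second comparison was between the subgenomes. A promoter peak was found at 9499 genes on P. alba and 8725 genes on P. tremula, and 7689 gene identifiers had one on both, which is 80.9% of the former and 88.1% of the latter. On P. alba alone 1810 genes had a promoter peak, and on P. tremula alone 1036. Such genes could still have signal below the p threshold, or a peak outside promoters, on the other subgenome. These counts therefore do not show binding at 1 parental copy alone. Position by position, 12576 peaks could be paired, which is 66.3% of P. alba and 73.8% of P. tremula peaks. The folds of paired peaks were close: across pairs, which are not independent replicates, Spearman's rho was 0.828, the median log2 ratio of P. alba to P. tremula was -0.00 with an SD of 0.18, and 249 pairs (1.98%) differed by more than 1.5 times. The summit pileups were identical in 9637 pairs (76.6%, 75.9 to 77.4%), so the lists are not independent measurements of the 2 subgenomes. Of the 6399 unpaired P. alba peaks, 57.6% were annotated to a gene that had a peak elsewhere on P. tremula, and of the 4464 unpaired P. tremula peaks 62.5% had one on P. alba.

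**Figure D4:**
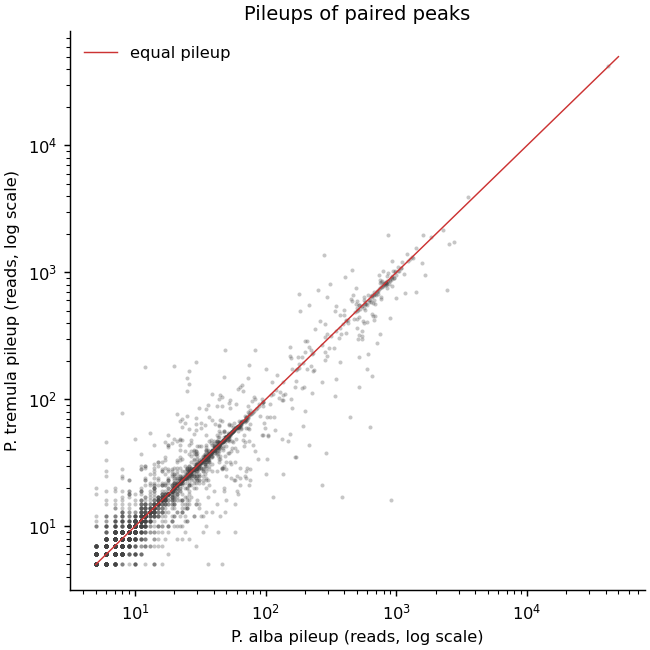
Summit pileup (reads, log scale) on P. tremula against that on P. alba for the 12576 paired peaks, 1 point per pair, with the line of equal pileup. The pileups are identical in 76.6% of pairs, and those points lie on the line.

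The strongest promoter peak was the same on both subgenomes. It covered the gene Potri.014G104800 on chromosome 14. On P. alba it ran from 8224506 to 8225967 with 1347 reads at the summit and a fold of 677.7, and on P. tremula from 8222290 to 8223741 with 1299 reads and a fold of 655.0. It lay inside the gene, which spans 8224319 to 8226114 on P. alba on the minus strand, and covered 81.4% of its length there and 81.3% on P. tremula. The recovered background at it was at the floor in both lists. The files do not pair this or any other identifier with a gene name.

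**Figure D5:**
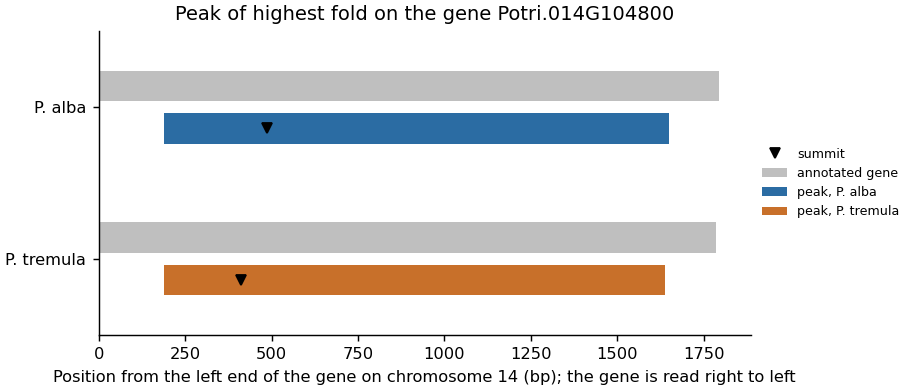
Map of the peak of highest fold (coloured bar, summit as a triangle) and the gene Potri.014G104800 (grey bar) on each subgenome, with the position from the left end of the gene in bp. The peak covers 81.4% of the gene on P. alba and 81.3% on P. tremula and ends short of the gene on both sides.

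The third highest promoter fold in each list was at Potri.001G206900 on chromosome 1, where a peak covered 76.8% of the gene on P. alba (20692259 to 20693130, fold 40.1, 113 reads) and 75.9% on P. tremula (20693717 to 20694587, fold 36.5, 111 reads). A gene on chromosome 2 had a peak 115 bp past its start on P. alba (13810638 to 13810773) with a fold of 41.7, and its P. tremula partner (13808051 to 13808213) had 20.2. A gene on chromosome 3 had its strongest P. alba peak at 2703587 to 2704113 (fold 22.7) and its strongest P. tremula peak at 2703267 to 2703427 (fold 24.1), both inside the gene. Peaks 866 and 862 bp upstream of a gene on chromosome 12 held 52 reads in each list. Peaks 805 and 803 bp upstream of a gene on chromosome 13 had a fold of 15.1 in each list. Of the 10 genes with the highest promoter fold, 6 were shared between the lists, and in each list 6 of the 10 summits were inside the gene.

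Some strong promoter peaks differed between the subgenomes. The second strongest on P. tremula, 595 bp upstream of a gene on chromosome 3 (8197694 to 8197775), had 153 reads and a fold of 77.6, and its gene had no promoter peak on P. alba. A P. alba peak on chromosome 1, 1413 bp upstream of its gene (9188686 to 9188780), had a fold of 29.7 against 5.04 for its P. tremula partner. A P. alba peak at the start of a gene on chromosome 9 (6370323 to 6370457) had 15.1 against 4.03. A P. tremula peak inside a gene on chromosome 14 (16234948 to 16235148) had 16.3 against 7.15, with a background of 12.6 reads. A gene on chromosome 8 had a P. tremula peak of fold 18.4 (19101521 to 19101898) and a highest promoter fold of 12.1 on P. alba. The remaining genes of the rule had folds close in both lists: on chromosome 14 at 5266479 to 5266598 on P. alba (15.5, and 13.4 on P. tremula), on chromosome 2 at 10906784 to 10906864 on P. alba (15.1, and 12.6), and on scaffold_41 at 90654 to 90872 on P. tremula (15.5, and 14.3 on P. alba). None of these differences has a replicate check.

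Outside promoters, the highest P. tremula fold was 32.7 in a distal intergenic peak on chromosome 7 (3910728 to 3910824), and the distal peak upstream of the same gene on P. alba (3911424 to 3911520) had 21.1. The highest P. alba fold outside promoters was 24.6, on scaffold_289 (13595 to 13681).

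The deepest peaks had low folds. The highest pileup, 41401 reads on P. alba and 42188 on P. tremula, was on chromosome 5, 944 bp upstream of Potri.005G113500 (8707068 to 8707919 on P. alba), where the fold was 4.73 and 4.60 over a background of 8752 and 9174 reads. Pileups of 500 reads or more were found at 213 P. alba and 206 P. tremula peaks, with a median fold of 2.80 and 2.64 against 3.52 and 3.53 in all others. The p threshold admits deep peaks at lower folds: the lowest fold was 1.44 and 1.502 at this depth, against 2.58 and 2.66 among peaks under 10 reads. Of these, 93 and 99 lay between 14600000 and 14899999 on chromosome 13, among them the P. alba peak over the start of Potri.013G140100 (14764405 to 14765963, 2773 reads, fold 2.98). The promoter class held 83.6% and 85.4% of the peaks of this depth, against 60.4% and 60.6% of the others.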

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

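Of 88 alternative values, 45 kept within the limits set, 40 moved, 2 passed a threshold that the reported value had not, and 1 changed direction. These limits were wider for counts than for shares, so the 45 include large changes. Shared genes counted as kept at 10977 when called by any peak, against 7689 reported. Pairs counted as kept at 8788 with q at or under 0.05, against 12576. At or above the median fold, the P. alba share of summits within 250 bp of a start counted as moved (12.9% against 11.8%). Peak and gene counts moved with the threshold, and the promoter share moved most with the distance that defines a promoter. With q at or under 0.01, 7556 P. alba and 6833 P. tremula peaks were left, promoter shares fell to 55.6% and 55.9%, distal shares rose to 34.8% and 34.6%, and 2840 genes had a promoter peak in both lists. At or above the median fold, the values were 11476 and 10075 peaks, 62.0% and 62.6% in promoters, 25.8% and 25.3% distal, and 4862 shared genes. Counts fell because fewer peaks were kept, and the cause of the shifts in shares was not tested. Promoters within 1 kb held 30.0% and 30.4% of peaks, those within 2 kb 47.6% and 47.8%, and 4171 genes were shared when called within 1 kb. With −log10 q as the strength, promoter medians were lower by the signed differences -0.176 and -0.180 (permutation p = 1e-05 each). The tests of pairs and of peaks without a partner, the 0.05 q threshold, the limit to chromosomes and the removal of peaks of 500 reads or more were chosen after seeing the data. Pairs numbered 4495 at q under 0.01 and 7451 at or above the median fold. The 0.05 q threshold gave promoter shares of 59.6% and 59.9% and distal shares of 28.8% in each list, and the 19 chromosomes alone gave 62.0% and 62.3% in promoters and 25.3% and 25.2% distal. The promoter odds ratio between subgenomes (0.991) stayed between 0.9735 and 0.993 in the other alternatives run, with no Fisher's exact p under 0.345. Among peaks without a partner the odds ratio was reversed to 1.24 (Fisher's exact p = 4.00e-08). That value goes arithmetically with near-equal whole-list and paired shares and unequal paired fractions (66.3% of P. alba and 73.8% of P. tremula peaks). Whether it reflects a promoter difference between the subgenomes was not tested. Merging overlapping intervals changed nothing, because no peaks overlap (the smallest gap is 79 bp). The share of pairs with identical pileup ranged from 68.6% at q under 0.01 to 81.3% at or above the median fold. No paired analysis was possible because the tables hold no value per library, and for the same reason no replicate could be left out. Motif shares, gene list tests and ChIP against input fits were not run. Depth limits the typical peak, since the median summit of 7 reads has a Poisson interval of 2.81 to 14.4, and limits the deepest peaks far less.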

Other observations

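All tests in this part were chosen after the result was seen. Peaks were spread over all 19 chromosomes. Counted to the highest annotated position, their density ran from 37.96 per Mb on chromosome 19 to 53.3 on chromosome 8 of P. alba, and from 32.1 to 48.7 on the same chromosomes of P. tremula. Most genes had 1 peak (9633 on P. alba, 9296 on P. tremula), 1046 and 805 had 3 or more, and the most at 1 gene was 25 and 23. Near gene ends, the last 250 bp of genes held 531 P. alba and 472 P. tremula summits, and the first 250 bp past the end 286 and 273. Each summit was measured only against the gene assigned to it. Summits past a gene's end that were assigned to another gene are thus not counted, so these counts do not show a drop in binding there. Peaks that covered over 50% of a gene were more frequent at genes with a fold of 10 or more, with 14 of 143 such genes on P. alba against 113 of 13260 others (odds ratio 12.6, 7.06 to 22.6, Fisher's exact p = 7.20e-11). On P. tremula they were 12 of 104 against 98 of 12383 (odds ratio 16.4, 8.68 to 30.8, Fisher's exact p = 1.04e-10). Neither read depth nor gene length was held fixed, so these tests do not separate fold from them. The median coverage at genes with a fold of 10 or more was 0% in both lists.

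Paired peaks of the subgenomes often held exactly the same number of reads. For pairs of 20 to under 200 reads, 37.0% (34.1 to 40.0%) were identical, while independent reads with a common mean gave 4.73% on average over 1000 simulated sets, with 5.98% as the upper end of their central 95% range. This argues against separate reads from each parental copy, and is consistent with the same reads having been aligned to each parental sequence in turn. The likeness of the lists would then say little about whether both parental copies are bound. At 200 reads or more the identical share was 2.54% (0.829 to 5.82%), within the simulated range, which reached 3.05%. Exact identity is rare at this depth in the simulation too (1.24% on average), so this class weighs neither way.

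The peak of highest fold filled 81.4% of the gene Potri.014G104800 on P. alba and stopped inside both gene ends. The background recovered at the peak was 0.989 reads, the floor of the list, under a summit of 1347 reads, so the caller's background held no excess there. The peak was chosen for its fold, and the background was computed from fold and pileup, so its low value is partly tied to that choice. Construct DNA in the ChIP and in the caller's background alike would raise that background. It was 0.989 reads on P. alba and 0.985 on P. tremula, the floor of each list, which argues against that explanation at this peak. Whether the input libraries gave the caller's background is not stated in the sources used here. Construct DNA in those libraries is therefore not excluded. DNA of this gene in the ChIP library only stays open, since the 81.4% coverage is the observation itself and no test of it. Binding along the chromosomal gene stays open too. The length of the peak was at the 95.3rd percentile of P. alba peaks with 500 reads or more. Those peaks had a median fold of 2.80 over a median background of 283.7 reads, so they are unlike this peak and the percentile is no test. The identifier is paired with no name, so whether it encodes the expressed factor was not tested.

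Of the P. alba peaks of 500 reads or more, 43.7% lay in 1 window on chromosome 13, and the median fold of all 213 such peaks was 2.80. In 99.53% of them on P. alba the recovered background was over 10 times the floor, with a median of 283.7 reads, the exception being the peak on Potri.014G104800. The background was computed from pileup and fold, so these values restate the high pileups and low folds to be explained, and DNA present in many copies in ChIP and control alike stays open. Binding of the factor at these sites cannot be told apart from it, since the p threshold admits deep peaks at lower folds (lowest fold 1.44, against 2.58 under 10 reads), so that their median fold weighs neither way. Without these peaks, the P. alba promoter share was 60.4%, so that share hardly depends on them.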
